A study of Mus musculus with 2 samples.

How the data were processed

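Immune cells carrying CD45.1, the NOD allele of the pan-leukocyte surface protein CD45, were sorted by flow cytometry from the pancreatic islets of female NOD/ShiLtJ mice, per the labels' protocols. NOD mice are an inbred strain that spontaneously develops autoimmune diabetes. Cells were taken at 7 weeks and at 12 weeks of age, and 1 droplet library (10x Genomics Chromium, 3' chemistry) represents each age. The labels do not say how many mice were pooled. The authors deposited, for each library, a matrix of whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, with 27998 genes. Cell Ranger 1.3.1 and the mouse build mm10 are named in the submitters' processing notes, and the annotation they counted against was not given in the sources used here. The 7 week matrix held 1113 barcodes and 8701184 UMIs, and the 12 week matrix 2812 barcodes and 19288252 UMIs. The smallest barcode held 2587 UMIs at 7 weeks and 3031 at 12 weeks. T cell receptor and immunoglobulin constant genes were absent from the gene list of these matrices.

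Barcodes were kept with at least 200 detected genes and at most 10% mitochondrial UMIs, which removed 4 barcodes at 7 weeks and 8 at 12 weeks. Doublets were scored per library by the Scrublet method with exact neighbours, from 2 simulated doublets per barcode. The automatic threshold called 0.535% of barcodes at 12 weeks, against 2.24% anticipated from a loading rate of 0.8% per 1000 barcodes, and it was used there (15 barcodes). At 7 weeks it called 0.180%, under the preset lower limit of 0.5%, so the barcodes with the highest scores were removed up to the loading rate (10 barcodes). The doublet filter was therefore not set alike in the 2 libraries, and 1099 and 2789 cells remained. Both libraries were clustered together. UMIs were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen without receptor and immunoglobulin segments, and 30 principal components and 15 neighbours were used. Leiden clustering was run at resolution 1 with seed 0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, matplotlib 3.10.9). A cluster took a class name with the ending "-like" only when that class led among its 10 leading genes by fold (prior 0.05), no other class had 3 or more markers there, and at least 3 markers of the class had a UMI in at least 10% of its cells. Markers of the T cell subsets counted for the T cell class where Cd4, Cd8a or Cd8b1 had a UMI in at least 25% of a cluster's cells, a condition set after the clusters were seen, because natural killer cells share several of these markers. It left cluster 10 unnamed. Clusters without a name are given by number.

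Within T cell-like clusters, CD8 T cells were those with a UMI of Cd8a or Cd8b1 and none of Cd4, and CD4 T cells the reverse, so that the genes compared did not set the class. The CD4 T class was near its limit in many cells, since 94 of 303 cells at 7 weeks and 264 of 738 at 12 weeks held 1 Cd4 UMI. For CD8 T cells, 8 of 141 and 34 of 419 held 1 Cd8 UMI. UMIs were summed per library and class, divided by the class total and expressed as CPM. Genes and lists were compared in classes with at least 50 cells in each library, and all kept cells were also compared together. The sum of each gene carries an exact Poisson 95% interval, the 12 over 7 week CPM ratio an exact conditional binomial 95% interval, and shares an exact (Clopper-Pearson) binomial interval. Differences of shares carry Newcombe intervals. With 1 library per age there is no test, and every interval covers counting error only, not the spread between mice, libraries or cells. A ratio against 0 counts uses a floor of 3 counts.

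The genes named follow a rule chosen before the data were examined. Eligible genes had a UMI in at least 10% of the cells of either library and at least 50 UMIs over both. Receptor segments, ribosomal protein and mitochondrial genes, unnamed models and Cd4, Cd8a and Cd8b1 were not counted. Genes were ranked by the bound of the ratio's interval nearest to 1. The 10 furthest on either side were named in CD8 T, CD4 T and B cell-like cells, and the 5 furthest in every other class. From each of the fixed gene lists 2 to 4 members were picked, those with the most UMIs and those with the largest ratio by the same bound, and the text gives a part of them. As an addition made after seeing the data, the ranking was repeated without the acinar, endocrine and haemoglobin lists. The 22 fixed lists cover T cell, B cell and myeloid programmes, antigen presentation, interferon responses, the cell cycle, immediate early genes and transcripts of pancreatic and red blood cells. For each list the median log2 ratio over members with at least 10 UMIs was set against 10000 random lists of the same size matched in 20 bins of expression. Its percentile describes these libraries and is not a test. The interval of a median comes from 400 Poisson redraws of the counts. Shares of cells with a UMI were also computed after thinning each cell to 3503 UMIs, the 10th percentile of kept cells. No interval was computed for differences of thinned shares. Where the intervals of 2 thinned shares overlap, this does not show that the shares were alike.

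Ratios were recomputed with TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors (R 4.3.3), with each cell weighted equally, with doublets kept, with other clusterings, and without cycling cells, which held 2 or more UMIs over Mki67, Top2a, Birc5, Cdk1 and Rrm2. Other settings varied the barcode filters, the resolution (0.5 and 2), the joint clustering, the share denominator and the UMI minimum of the lists (1 and 50). Settings added after seeing the data subtracted from each ratio the median of genes of like GC content, added the T cells of clusters 6 and 20 to the T cell subsets, left out barcodes with over 10% pancreatic or haemoglobin transcripts, and left cycling cells out of the lists. Gene positions came from GENCODE M21 on GRCm38, the assembly that mm10 names. The share of 60-base words that the last 500 bases of each gene's longest transcript hold in common with other genes was computed from the same annotation. Genes sharing 20% or more, such as Mzb1, Tuba1b, Hspa8, Mif, Psme2 and Try5, can exchange reads with near copies and their values are uncertain, as are those of the Klra and MHC class I families.

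The interval step was tested on simulated counts with 200 genes given known folds. Each sum was drawn from a Poisson distribution, the model that the intervals assume. In the CD4 T simulation over 7103 genes, the interval lay on the right side of 1 for 98% of genes at 2-fold higher, 93.2% at a ratio of 0.5, 72% at 1.5 and 76.6% at 0.67. In the CD8 T simulation over 5217 genes these shares were 88%, 97.4%, 66% and 58.1%, and in the B cell-like simulation over 6275 genes 94%, 78%, 60% and 50%. Among unchanged genes the interval excluded 1 for 4.47%, 4.21% and 3.74% in the CD4 T, CD8 T and B cell-like simulations. These shares hold for counting error alone. They do not give the error rate in the real counts, where UMIs of some genes sat in few cells. Called doublets and filtered barcodes were left out, and genes were ranked and list intervals computed only within classes of at least 50 cells in each library. UMI counts of single genes and the median of 1 gene set in smaller classes stand in the closing section. A few genes that the naming rule picked are not reported here.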

Results

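Single-cell transcriptomes were measured from CD45.1+ cells of the pancreatic islets of female NOD mice at 7 and at 12 weeks of age, with 1 library per age. The comparison asks which immune cells were in the islets at each age and how their transcripts differed. After filtering, 1099 cells with a median of 5636 UMIs and 1798 genes were kept at 7 weeks, and 2789 cells with a median of 4954 UMIs and 1612 genes at 12 weeks. Without replicate libraries, a difference below is one between these 2 libraries.

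T cell-like cells made up most of both libraries, at 54.3% (51.3 to 57.3, 597 cells) at 7 weeks and 53.6% (51.8 to 55.5, 1496 cells) at 12 weeks, a difference of -0.683 percentage points with an interval of -4.15 to 2.80. B cell-like cells, led by Cd79a, Cd74 and Ebf1, held a larger share at 12 weeks, 23.6% (22.1 to 25.2, 659 cells) against 15.9% (13.8 to 18.2, 175 cells), a difference of 7.70 points (4.95 to 10.3). Natural killer (NK) cell-like cells, led by Gzma and the Klra receptors, held a smaller share at 12 weeks, 0.645% (18 cells) against 2.27% (25 cells), a difference of -1.63 points (-2.72 to -0.811). Cluster 10, led by the activating NK receptor gene Ncr1, Ccl5 and the chemokine gene Xcl1, was also smaller, at 2.29% against 6.0%, a difference of -3.71 points (-5.35 to -2.31). All of these shares are of cells that passed the CD45.1 sort and the barcode filters, and the median depth was higher at 7 weeks. With unnamed and non-leukocyte clusters left out of the denominator, the T cell-like difference was -4.63 points.

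Cluster 6, led by the proliferation genes Stmn1, Birc5 and Rrm2, held 6.46% of cells at 7 weeks and 5.95% at 12 weeks, and cluster 7, led by Ifitm3 and the MHC class II gene Cd74, held 5.55% and 5.95%. Plasmacytoid dendritic cell-like cells, led by Siglech, held 2.46% and 1.94%. For these 3 the interval of the difference included 0. Cluster 15, led by 5430421N21Rik, the chemokine receptor gene Cxcr6 and the gamma-delta T cell marker Cd163l1, held 1.73% and 0.789%. Cluster 20, led by the interferon-induced genes Ifit1, Isg15 and Ifit3, held 1.09% and 0.287%, from 12 and 8 cells. Innate lymphoid cell-like cells held 1.09% and 0.717%, and conventional dendritic cell 1-like cells 1.0% and 0.825%, with intervals of the difference that included 0. With each library clustered alone, the differences were 1.25 points for innate lymphoid cell-like cells in place of -0.375, 0.789 for conventional dendritic cell 1-like cells in place of -0.176, -1.71 for cluster 7 in place of 0.401 and -2.73 for cluster 15 in place of -0.94. Macrophage-like cells (16 and 43 cells) and plasma cell-like cells (5 and 19 cells) were seen at both ages, but 5 of the 10 leading genes of each differed between ages within the cluster, so their sizes are not compared.

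**Figure D1:**
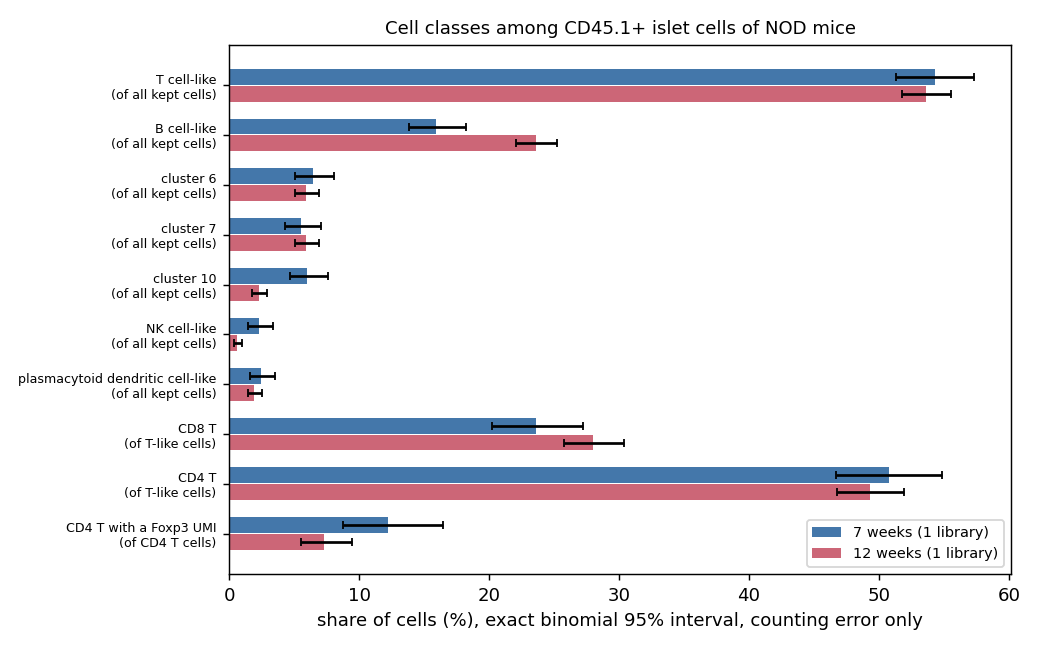
Horizontal bars give the share of cells in percent at 7 weeks (blue) and 12 weeks (red), 1 library each, with exact binomial 95% intervals that cover counting error only; the denominator stands under each name. B cell-like cells are higher at 12 weeks (23.6% against 15.9%), and NK cell-like cells and cluster 10 are lower.

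Among T cell-like cells, CD8 T cells made up 23.6% (20.3 to 27.2, 141 cells) at 7 weeks and 28.0% (25.7 to 30.4, 419 cells) at 12 weeks, a difference of 4.39 points (0.189 to 8.37). With every cell thinned to 3503 UMIs these shares were 25.3% and 30.6%. CD4 T cells made up 50.8% and 49.3%, a difference of -1.42 points (-6.15 to 3.31). T cell-like cells with UMIs of both co-receptors made up 6.36% and 6.88%, and those with neither 19.3% and 15.8%. A UMI of Foxp3, the transcription factor of regulatory T cells, was found in 12.2% (8.74 to 16.4) of CD4 T cells at 7 weeks and 7.32% (5.54 to 9.44) at 12 weeks, a difference of -4.89 points (-9.38 to -1.05). Over the same cells thinned to 3503 UMIs, leaving out 32 and 96 shallower ones, the shares were 10.3% and 5.45%. In thinned B cell-like cells, which should lack Foxp3, they were 0.649% and 0.164%. With T cells assigned by named sub-clusters, CD4 T cells made up 73.0% and 70.1% of T cell-like cells. Of these, 14.2% and 6.01% lay in sub-clusters where Foxp3 had a UMI in at least 25% of cells, a difference of -8.21 points. That measure counts whole sub-clusters and not cells with a Foxp3 UMI. Such a UMI was found in 69.15% of the cells of 1 sub-cluster and 35.5% of the other. The median depth of CD4 T cells was 5530 and 4519 UMIs, and of B cell-like cells 5065 and 4658.

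Transcripts of pancreatic cells were found in every compared class and were higher at 12 weeks. Acinar transcripts, which encode digestive enzymes, amounted to 0.341 UMIs per 10000 (0.265 to 0.432) in CD4 T cells at 7 weeks and 2.78 (2.62 to 2.95) at 12 weeks, and to 0.167 and 2.54 in B cell-like cells. Their list median was higher by 2.46, 2.10 and 2.25 on the log2 scale in CD4 T, CD8 T and B cell-like cells. In clusters 10, 6 and 7 it was higher by 2.98, 2.19 and 1.95. Members with 0 UMIs at 7 weeks were 8 of 14 in CD8 T cells, 7 of 14 in B cell-like cells and 2 of 3 in cluster 10. Their ratios use the floor of 3 counts, which makes them smaller. The acinar medians can therefore understate the difference, and the order of the classes is not read from them. The UMIs per 10000 do not use the floor. Islet endocrine transcripts were higher by 1.89, 1.22 and 2.38 in CD4 T, CD8 T and B cell-like cells and by 2.82 and 1.43 in clusters 6 and 7. The endocrine genes Gcg, encoding glucagon, and Ins2, encoding insulin, and the acinar genes Ctrb1, encoding a chymotrypsinogen, and Prss2, encoding a trypsinogen, stood among the 10 highest genes by rule. In CD4 T cells the ratios were 8.30 (5.16 to 14.2) for Gcg, 6.87 (3.91 to 13.2) for Ins2, 8.21 (4.96 to 14.6) for Ctrb1 and 15.3 (6.39 to 47.7) for Prss2. The red blood cell list had a median of -0.76 (-0.79 to -0.73) in T cell-like cells, which held 18594 of the 18783 haemoglobin UMIs at 7 weeks, and -1.22 (-2.18 to -0.22) in CD8 T cells. These UMIs made up over 10% of 1 barcode at 7 weeks and 2 at 12 weeks, all within named immune classes. In CD4 T cells (-0.58, -1.18 to 0.55), B cell-like cells (-0.67, -1.11 to 0.13) and cluster 7 (-0.12, -1.46 to 0.69) its interval included 0, and in cluster 10 its UMIs amounted to 0.25 and 0.267 per 10000. The genes named below leave these lists out.

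**Figure D2:**
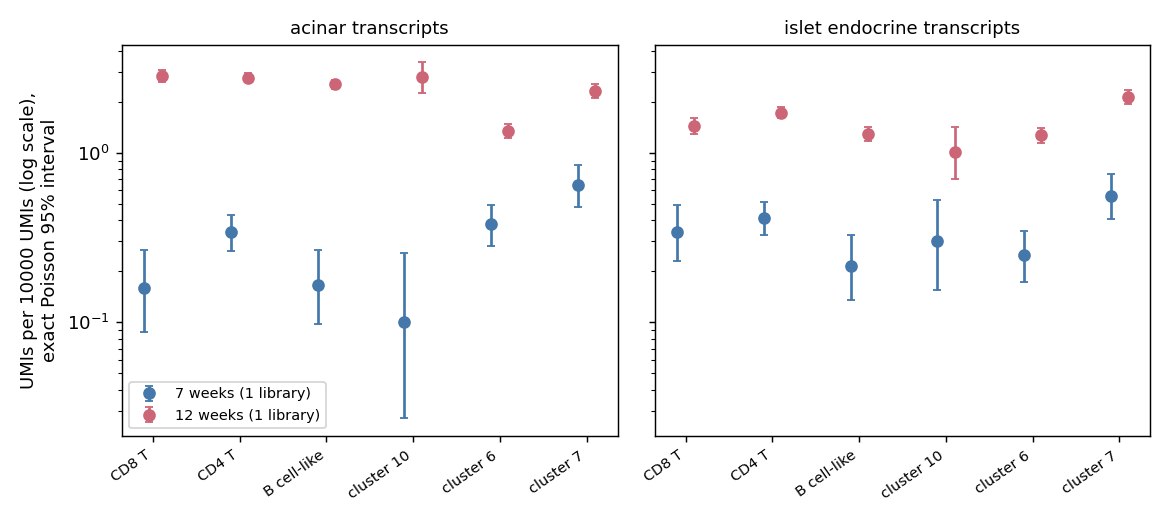
UMIs of acinar and islet endocrine transcripts per 10000 UMIs (log axis) in 6 cell classes at 7 weeks (blue) and 12 weeks (red), 1 library each, with exact Poisson 95% intervals covering counting error only. Acinar transcripts are higher at 12 weeks in every class shown, for example 2.78 against 0.341 in CD4 T cells.

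In CD4 T cells, genes of naive and recirculating T cells were higher at 12 weeks. Il7r, encoding the interleukin 7 receptor that sustains naive and memory T cells (chromosome 15, 9505788 to 9530176, GRCm38), stood at 70.7 CPM at 7 weeks and 181 CPM at 12 weeks, a ratio of 2.56 (2.14 to 3.10). Lef1, encoding a transcription factor of naive T cells (chromosome 3, 131110471 to 131224356), stood at 141 and 279 CPM, a ratio of 1.98 (1.73 to 2.26). Ccr7, encoding a lymph node homing receptor, had a ratio of 2.12 (1.80 to 2.51), and Dapl1 one of 2.60 (2.11 to 3.22), with 57.4% of its 7 week UMIs in 5 cells. Of the 16 measured naive and memory T cell genes 11 were higher, with a median log2 ratio of 0.16 (0.08 to 0.36) at the 99.6th percentile of matched random lists, while Cd27 had a ratio of 0.969 (0.880 to 1.07). After thinning, an Il7r UMI was found in 20.7% of CD4 T cells at 7 weeks and 34.0% at 12 weeks, and a Lef1 UMI in 27.7% and 45.8%, against 3.25% and 0.328% of B cell-like cells for Il7r and 3.25% and 2.13% for Lef1. Unthinned, these shares were 24.1% and 40.2% for Il7r and 38.3% and 52.2% for Lef1. The cluster with the most CD4 T cells was cluster 2, led by Tbc1d4 and Tnfsf8, at 7 weeks (126 of 303 cells) and cluster 1, led by Igfbp4 and Lef1, at 12 weeks (230 of 738 cells, against 41 at 7 weeks). Outside cluster 1 the list median was -0.13 (-0.33 to 0.02), with Il7r at 2.23 (1.80 to 2.79) and Dapl1 at 0.566 (0.361 to 0.883).

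Other genes higher in CD4 T cells at 12 weeks were Tsc22d3, encoding the glucocorticoid-induced leucine zipper protein, at a ratio of 2.85 (2.41 to 3.39), Plaur, encoding the urokinase receptor, at 4.59 (2.58 to 8.88), Pdlim4 at 3.78 (2.48 to 5.99), Sfi1 at 2.94 (1.84 to 4.93) and Lyz2, encoding the lysozyme of myeloid cells, at 2.57 (1.80 to 3.74). Of the 188 Lyz2 UMIs of CD4 T cells at 12 weeks 51 sat in 1 cell, and macrophage-like cells held 12234. Ccl5, encoding a T cell chemokine, had a ratio of 1.90 (1.78 to 2.04), with 46.0% and 36.2% of its UMIs in 5 cells. Ccl4, another chemokine gene, had one of 0.736 (0.686 to 0.790), with 83.65% and 55.45% of its UMIs in 5 cells. After thinning, a Ccl5 UMI was found in 34.7% and 38.9% of CD4 T cells, against 31.8% and 25.4% of B cell-like cells (45.9% and 44.9% of CD4 T cells unthinned). Of 18 interferon gamma response genes 14 were higher, with a median log2 ratio of 0.29 (0.10 to 0.55) at the 100th percentile, among them the guanosine triphosphatase genes Gbp7 at 1.66 (1.37 to 2.01) and Iigp1 at 1.82 (1.40 to 2.39), while Irf1 stood at 1.02 (0.897 to 1.17). Lists of other immune cell types went both ways in these cells. Medians were 0.44 (0.27 to 0.63) for MHC class II genes and 0.32 (0.04 to 0.55) for resting B cell genes. The inflammatory myeloid list stood at -0.44 (-0.74 to -0.14), with 3 of 11 members higher. The antibody secretion (0.03), activated B cell (0.03), dendritic cell activation (0.18), resident macrophage (0.27) and lysosome (0.05) lists had intervals that included 0. The 19 MHC class I presentation genes had a median of 0.13 (0.08 to 0.18), with B2m at 1.15 (1.12 to 1.17), the proteasome gene Psmb8 at 1.20 (1.13 to 1.28) and Nlrc5 at 0.623 (0.458 to 0.849). The type I interferon list had a median of 0.05 (-0.12 to 0.25).

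Regulatory and inhibitory genes were lower in CD4 T cells at 12 weeks. Of 16 regulatory T cell genes 3 were higher, and the median was -0.26 (-0.43 to -0.16) at the 0.450th percentile. The anti-inflammatory cytokine gene Il10 had a ratio of 0.486 (0.399 to 0.591), with 60.1% of its UMIs in 5 cells at 7 weeks, and the integrin gene Itgae 0.329 (0.232 to 0.463), while Tnfrsf4 stood at 1.11 (1.02 to 1.21) and Izumo1r at 0.958 (0.889 to 1.03). Of 14 inhibitory receptor and exhaustion genes 3 were higher, with a median of -0.31 (-0.52 to -0.21), or -0.16 with the CD4 T cells of clusters 6 and 20 added. The nuclear receptor gene Nr4a2 had a ratio of 0.431 (0.337 to 0.552), Cd160 one of 0.340 (0.180 to 0.627), with 65.5% of its 7 week UMIs in 5 cells, and Cd200 one of 0.792 (0.712 to 0.882), whereas Lag3 stood at 1.19 (1.09 to 1.29). T cell homing receptors had a median of -0.21, with Itgb1 at 0.796 (0.727 to 0.873). The cytotoxic list (-0.07, -0.34 to 0.18), the follicular and helper list (-0.07, -0.18 to 0.11, with Tnfsf8 at 1.32 and Tnfsf11 at 0.763) and the cell cycle list (-0.08, -0.25 to 0.13) had intervals that included 0.

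In CD8 T cells, 2 members of the tumour necrosis factor receptor family and the inhibitory receptor gene Havcr2 were higher at 12 weeks. Tnfrsf9, encoding the costimulatory receptor 4-1BB (chromosome 4, 150914562 to 150946102), stood at 29.7 and 77.8 CPM, a ratio of 2.62 (1.73 to 4.12), Tnfrsf4 had a ratio of 2.38 (1.42 to 4.24), with 50.9% of its 12 week UMIs in 5 cells, and Havcr2, from 6 UMIs in 5 cells at 7 weeks, 4.05 (1.77 to 11.4). After thinning, a Tnfrsf9 UMI was found in 7.94% (3.87 to 14.1) and 12.1% (9.04 to 15.8) of CD8 T cells, intervals that overlap, against 0.649% and 0.984% of B cell-like cells (8.51% and 15.5% of CD8 T cells unthinned). Tnfrsf18 of the same family stood at 1.18 (0.920 to 1.53). Thinning left out 15 and 31 CD8 T cells. Lag3 had a ratio of 1.35 (1.17 to 1.56), Lef1 1.62 (1.36 to 1.93) and Cd27 1.27 (1.10 to 1.46), while Klf3, encoding a transcription factor, had 0.464 (0.324 to 0.666) and Ctla4 0.585 (0.416 to 0.827). Cluster 4, led by Ccl5 and Nkg7, held 57.4% of CD8 T cells at 7 weeks and 45.6% at 12 weeks, cluster 5, led by Cd8b1 and Dapl1, 36.9% and 43.9%, and cluster 1, led by Igfbp4 and Lef1, 1.42% and 5.97%. Also named were Ctla2a, encoding a cysteine protease inhibitor, at 1.75 (1.5 to 2.04), Cd55, encoding a complement regulator, at 3.44 (1.49 to 9.77), and Smn1, Cpne4, Apool, Angel2, Adprhl2 and Ate1, whose ratios ran from 2.78 to 4.61 on 4 to 11 UMIs at 7 weeks. The Klra4 NK receptor gene had a ratio of 0.204 (0.114 to 0.356), with 63.2% of its 7 week UMIs in 5 cells.

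Cytotoxic genes differed in both directions in CD8 T cells. The granzyme genes Gzma and Gzmb had ratios of 0.256 (0.193 to 0.338) and 0.414 (0.329 to 0.520). At 7 weeks 5 cells held 96.9% of the Gzma UMIs and 79.6% of the Gzmb UMIs. Without cycling cells the Gzma log2 ratio was 0.11 in place of -1.96. With the CD8 T cells of clusters 6 and 20 added, the log2 ratios were 0.95 for Gzma and 0.06 for Gzmb. Nkg7 stood at 1.17 (1.10 to 1.23) and Ccl5, the most abundant member, at 0.986 (0.961 to 1.01). The list medians were -0.02 (-0.18 to 0.14) for cytotoxic genes, 0.01 (-0.11 to 0.16) for naive and memory genes, 0.01 (-0.22 to 0.28) for inhibitory receptors, 0.22 (-0.10 to 0.42) for regulatory genes, -0.35 (-0.63 to 0.16) for follicular and helper genes with Maf at 0.326 and Sh2d1a at 1.34, -0.13 for homing receptors with Cxcr4 at 0.491 and Itgb1 at 0.684, and 0.00 for the cell cycle. At 7 weeks 5 cells held 77.1% of the Maf UMIs and 58.3% of the Cxcr4 UMIs. Without cycling cells the cytotoxic median was 0.20 and the homing median 0.01. With the CD8 T cells of clusters 6 and 20 added, the cytotoxic, naive and homing medians were 0.27, 0.19 and 0.00, and with T subsets from sub-clusters the cell cycle median was -0.24. The MHC class I list had a median of 0.14 (0.05 to 0.18), with H2-T23 at 1.26 and B2m at 1.14. The type I interferon list had -0.16 (-0.38 to -0.01) with Rtp4 at 0.682 (0.473 to 0.995), and the interferon gamma list -0.01 (-0.12 to 0.33) with Irf1 at 0.753.

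In B cell-like cells, genes of antibody secretion and some genes of endoplasmic reticulum proteins were higher at 12 weeks. All 12 measured antibody secretion genes were higher, with a median log2 ratio of 0.73 (0.67 to 1.04) above every matched random list. Jchain, encoding the joining chain of secreted antibodies (chromosome 5, 88519809 to 88527891), stood at 69.7 and 191 CPM, a ratio of 2.73 (2.14 to 3.54). Hsp90b1, encoding an endoplasmic reticulum chaperone, had a ratio of 2.18 (1.92 to 2.48), Creld2 one of 3.08 (2.04 to 4.83), Pdia6 one of 2.21 (1.82 to 2.71), Mzb1 one of 1.71 (1.56 to 1.88) and the chaperone gene Hspa5 one of 1.5 (1.35 to 1.68). These UMIs were concentrated, with 5 of the 659 cells at 12 weeks holding 69.7% of those of Jchain, 61.7% of Creld2 and 54.7% of Hsp90b1. Without the 7 and 29 cycling cells the list median was 0.25. The log2 ratio of Jchain was -0.48 in place of 1.45 and that of Hsp90b1 0.03 in the same cells. The thinned share of B cell-like cells with a Jchain UMI was 16.2% (10.8 to 23) at 7 weeks and 13.3% (10.7 to 16.2) at 12 weeks, near the 11.8% and 13.2% of CD4 T cells, and is read as background. Thinning left out 21 and 49 B cell-like cells, and unthinned a Jchain UMI was found in 35 of 175 and 118 of 659 cells.

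Cell cycle genes were higher in B cell-like cells, with 17 of 24 members higher and a median of 0.41 (0.23 to 0.66). Rrm2, encoding a ribonucleotide reductase subunit, had a ratio of 5.03 (2.59 to 11.2) and Ube2c one of 2.92 (1.77 to 5.11), from 30 and 28 cells at 12 weeks, of which 5 held 65.7% and 86.0% of the UMIs. After thinning, an Rrm2 UMI was found in 1.95% and 2.30% of B cell-like cells (2.86% and 4.55% unthinned), below the 2.95% and 2.80% of CD4 T cells. With each cell weighted equally the Ube2c log2 ratio was 0.00 in place of 1.54. Cycling cells made up 4.0% and 4.40% of the class. Other higher genes were the actin-severing protein gene Gsn at 2.63 (1.83 to 3.89), Lgals1, encoding galectin 1, at 2.18 (1.69 to 2.86), Prdx1, encoding a peroxide-reducing enzyme, at 1.90 (1.66 to 2.17), and, on 4 to 9 UMIs at 7 weeks, Kat2a, Pold2 and Tsen15. The activated and germinal centre list had a median of -0.08 (-0.24 to 0.18). Resting B cell genes were lower, with 10 of 13 not higher and a median of -0.23 (-0.34 to -0.10). Among them Btg1, encoding an antiproliferative protein, had a ratio of 0.408 (0.383 to 0.436) and Klf2, encoding a quiescence factor, 0.541 (0.422 to 0.699), while Bank1 stood at 1.10 (1.0 to 1.21). Btg1 was also lower in CD8 T and CD4 T cells, at 0.499 and 0.534. MHC class II genes had a median of 0.17 (0.12 to 0.22) at the 85.5th percentile, or 0.09 with GC content subtracted, with H2-Aa at 1.16 and H2-Ab1 at 1.21. The type I interferon list had a median of 0.28 (0.02 to 0.50) with Bst2 at 1.46 and Ifi47 at 1.54, and the interferon gamma list one of 0.02 (-0.03 to 0.42), or -0.07 with GC content subtracted, with Gbp2 at 2.10 and Gbp3 at 2.08. Pim1 and Pkn2, which encode kinases, and Rab24 were lower, at 0.356 (0.274 to 0.465), 0.344 (0.247 to 0.480) and 0.305 (0.205 to 0.456). All 3 were also lower in CD8 T cells, at 0.365, 0.570 and 0.317, and in CD4 T cells, at 0.508, 0.511 and 0.303.

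**Figure D3:**
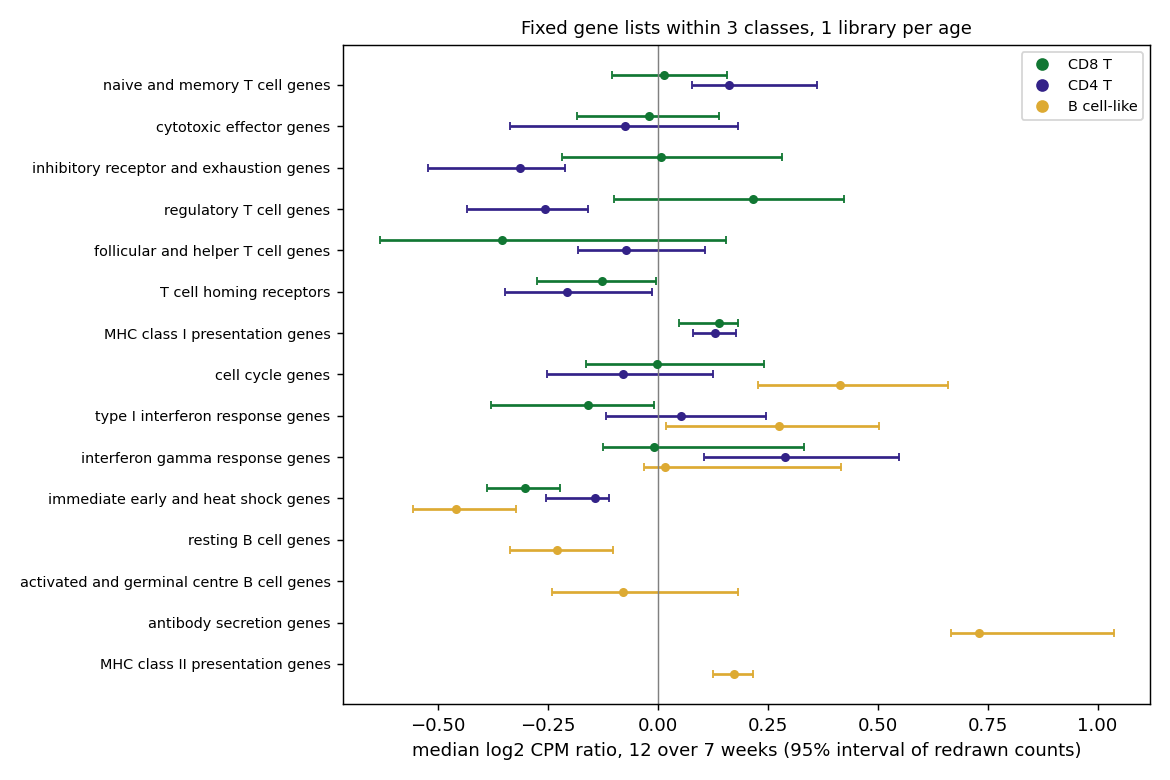
Points give the median log2 ratio of CPM at 12 over 7 weeks for the fixed lists of T cell, B cell and shared programmes in CD8 T (green), CD4 T (indigo) and B cell-like (yellow) cells, and bars the 95% interval over redrawn counts, which covers counting error only; acinar, endocrine, red blood cell and myeloid lists are not drawn. Among the medians drawn, that of antibody secretion genes in B cell-like cells stands furthest above 0 at 0.73, and immediate early genes lie below 0 in all 3 classes.

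Immediate early and heat shock genes, which also respond to tissue dissociation, were lower at 12 weeks in every class. The list median was -0.46 (-0.56 to -0.32) in B cell-like cells, -0.30 (-0.39 to -0.22) in CD8 T cells and -0.14 (-0.25 to -0.11) in CD4 T cells (-0.09 with TMM factors), and -0.42, -0.29 and -0.36 in clusters 6, 10 and 7. Ier5, an immediate early gene (chromosome 1, 155096361 to 155099636), had ratios of 0.161 (0.132 to 0.195), 0.269 (0.204 to 0.354) and 0.182 (0.148 to 0.223) in B cell-like, CD8 T and CD4 T cells. The heat shock gene Hspa1b stood at 0.318 and 0.32 in B cell-like and CD8 T cells, and the orphan nuclear receptor gene Nr4a1 at 0.391 (0.331 to 0.461) in CD4 T cells, while Hspa8 stood at 0.889 to 0.934 in these 3 classes. Several genes of other functions were lower in the same way: Glrx5, encoding a mitochondrial glutaredoxin, at 0.279, 0.184 and 0.212 in B cell-like, CD8 T and CD4 T cells, and the co-chaperone gene Bag1 at 0.305, 0.251 and 0.241. Tmem160, Lrrc58, Bloc1s4 and the antiproliferative gene Tob1 were lower in CD8 T and CD4 T cells. Cmas was lower in CD8 T cells, Zfp771 and the glutamate dehydrogenase gene Glud1 in CD4 T cells, and Bri3 in CD4 T and B cell-like cells. Over all cells together Ier5, Glrx5, Zfp771, Bri3 and Bag1 had the lowest ratios, from 0.191 to 0.255. The highest outside the pancreatic lists were Slpi, encoding a protease inhibitor, at 2.78, the fatty acid binding protein gene Fabp5 at 2.48, Gsn at 2.22, the B cell gene Ms4a1, encoding CD20, at 2.13 and Lyz2 at 1.90. Plasma cell-like cells held the most Slpi UMIs of any class. These were 659 in 5 cells at 7 weeks and 5255 in 18 cells at 12 weeks. In all T cell-like cells together Plaur at 2.85, Pdlim4 at 2.73, Tsc22d3 at 2.11, Lyz2 at 2.29 and Ctla2a at 1.85 were highest, and Ier5, Glrx5, Zfp771, Tob1 and Bri3 lowest. Of the 331 Lyz2 UMIs of T cell-like cells at 12 weeks 51 sat in 1 cell.

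**Figure D4:**
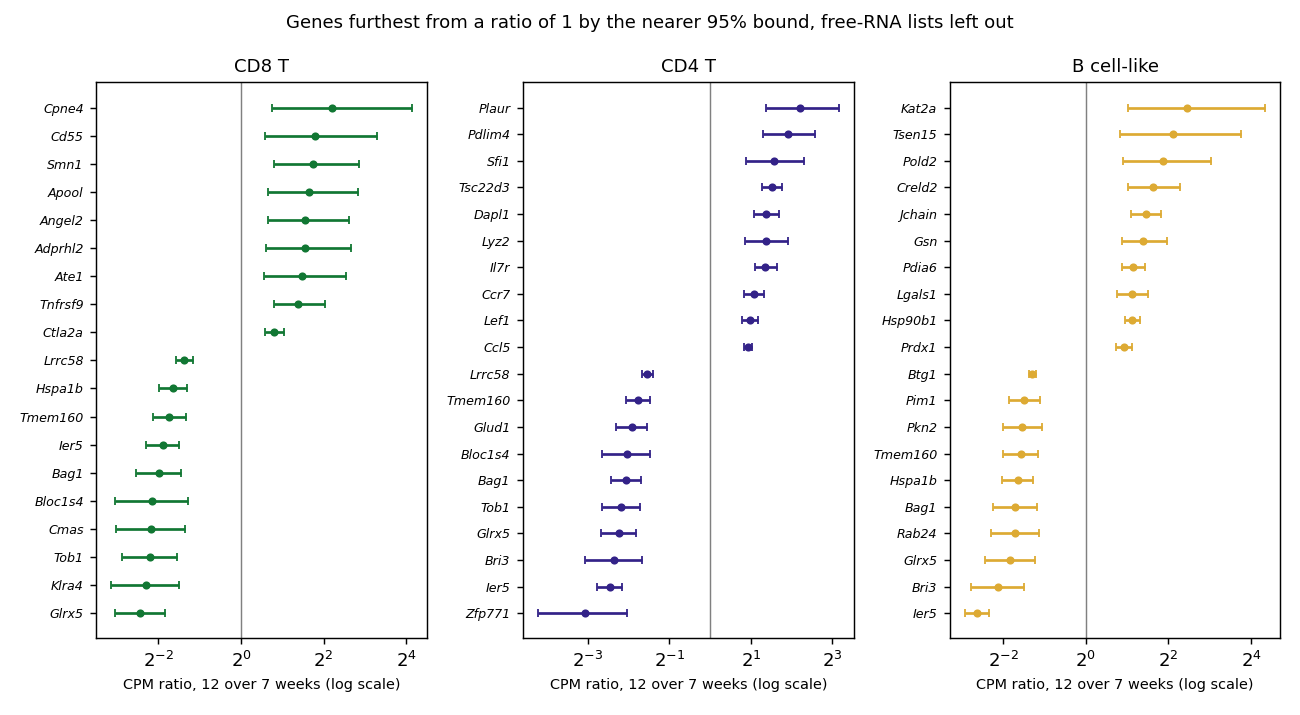
CPM ratio at 12 over 7 weeks (log axis) of the 10 genes furthest above and below 1 by the nearer bound in CD8 T, CD4 T and B cell-like cells, with the acinar, endocrine and haemoglobin lists and 1 higher gene of CD8 T cells left out; bars are exact 95% intervals covering counting error only. Il7r (2.56), Ccr7 (2.12) and Lef1 (1.98) are among the higher genes of CD4 T cells, and Ier5 is among the lower genes of all 3 classes.

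The cells of cluster 6 are mostly cycling (62 of 71 and 142 of 166). Over both ages a Cd4 UMI was found in 56.5% of them, a Cd8a UMI in 50.6%, a Foxp3 UMI in 10.55% and a Cd79a UMI in 17.7%. The cluster thus mixes T cell subsets, and whether their mix differed between the ages was not tested. In this cluster cytotoxic genes were higher at 12 weeks. Of 19 members 16 were higher, with a median log2 ratio of 0.71 (0.47 to 0.83). Gzma stood at 33.5 and 287 CPM, a ratio of 8.55 (6.37 to 11.7), from 6 and 21 cells, the chemokine genes Ccl3 and Ccl5 at 4.01 (3.23 to 5.02) and 1.79 (1.72 to 1.88), Gzmb at 2.90 (2.32 to 3.67) and Nkg7 at 1.24 (1.17 to 1.31). At 12 weeks 5 cells held 85.0% of the Gzma UMIs and 64.8% of the Gzmb UMIs. After thinning, a Gzmb UMI was found in 12.9% (6.05 to 23) and 18.2% (12.6 to 24.9) of these cells, intervals that overlap, against 0 and 0.328% of B cell-like cells (16.9% and 25.9% of cluster 6 unthinned). Inhibitory receptors had a median of 0.32 (0.11 to 0.56), with Havcr2 at 4.66 (2.34 to 10.5) and Lag3 at 1.74 (1.51 to 2.02). Follicular and helper genes had one of 0.63 (0.36 to 0.76), with Tnfsf11 at 2.97 (1.86 to 4.97), Maf at 1.69 and Sh2d1a at 1.42. The B cell attractant gene Cxcl13 had 1 UMI at 7 weeks and 53 at 12 weeks, a ratio of 25.8 (4.44 to 1.04e+03), with 67.9% of the 12 week UMIs in 5 cells. Its thinned share of cells was 0% (0 to 5.13) and 3.64% (1.35 to 7.75), intervals that overlap, against 0 and 1.31% of B cell-like cells (1.41% and 10.2% of cluster 6 unthinned). Naive and memory genes were lower, with a median of -0.24 (-0.44 to -0.04) and Tcf7 at 0.767. In the few cells of cluster 6 that were not cycling, the log2 ratio was 1.08 for Tcf7 in place of -0.38 and -0.62 for Nkg7 in place of 0.31. The MHC class I list had a median of 0.18 (0.16 to 0.28), or 0.12 with GC content subtracted, and the regulatory (0.22), homing (0.15), type I interferon (0.01) and interferon gamma (0.13) lists had intervals that included 0. Taf10, encoding a general transcription factor, was lower at 0.252.

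In cluster 10, Gadd45g, a stress response gene, had a ratio of 5.40 (3.30 to 9.25), with 75.8% of its 12 week UMIs in 5 cells. Its thinned share of cells was 18.0% (9.36 to 30) and 23.7% (13.6 to 36.6), intervals that overlap, near the 24.0% and 20.2% of B cell-like cells (19.7% and 29.7% of cluster 10 unthinned). Ms4a4b, encoding a lymphocyte membrane protein, had a ratio of 1.77 (1.55 to 2.03). Stmn1 (2.70) and Cd74 (3.38) were also named, but 5 cells held 98.0% and 67.0% of their 12 week UMIs. Polr2m stood at 0.244 (0.130 to 0.429) and the small G protein gene Gem at 0.329 (0.227 to 0.467). The NK receptor gene Klrd1 stood at 1.43 (1.19 to 1.72) within a cytotoxic list of median 0.13 (0.01 to 0.28) at the 80.8th percentile. Gzmb of the same list stood at 0.0847 (0.00200 to 0.557), from 14 UMIs in 4 cells and 1 UMI. Other genes higher at 12 weeks were the sphingosine phosphate receptor genes S1pr1 and S1pr4, at 2.32 (1.34 to 4.12) and 1.91 (1.20 to 3.10). Naive and memory genes had a median of 0.25 (0.05 to 0.53), homing receptors 0.31 (0.13 to 0.59), the MHC class I list 0.25 (0.09 to 0.29) and the 4 measured follicular and helper genes 0.74 (0.40 to 1.3). The inhibitory (-0.10, with Pdcd1 at 0.216 on 11 and 2 UMIs), regulatory (0.75, and -0.44 over members with at least 50 UMIs), cell cycle (0.25), type I interferon (0.17) and interferon gamma (-0.05) lists had intervals that included 0.

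Cluster 7 was mixed, and its genes of other cell classes differed between the ages: the T cell genes Cd3g and Thy1 were lower at 12 weeks, at 0.210 (0.147 to 0.297) and 0.183 (0.108 to 0.301), and the B cell gene Cd79a higher at 10.5 (3.46 to 52.0), with 62.8% of its 12 week UMIs in 5 cells. Its MHC class II list had a median of 0.16 (0.14 to 0.24), the MHC class I list 0.21 (0.18 to 0.28) and dendritic cell activation genes 0.24 (0.15 to 0.48). They lay at the 77.9th, 94.7th and 95.2nd percentiles of matched random lists. Of the last list, the amino acid oxidase gene Il4i1 stood at 1.66 (1.39 to 2.0). Socs2, from 1 UMI at 7 weeks, stood at 29.0 (5.05 to 1.16e+03), with 65.3% of its 12 week UMIs in 5 cells. Fabp5 stood at 3.54 (2.97 to 4.24) and Cd63 at 8.74 (3.91 to 24.2) within a lysosome and lipid handling list of median 0.02 (-0.01 to 0.45), which was -0.08 over members with at least 1 UMI and -0.02 with GC content subtracted. The interferon-induced chemokine genes Cxcl9 and Cxcl10 were lower at 0.685 (0.604 to 0.779) and 0.420 (0.343 to 0.514), and the interferon gamma (-0.01), type I interferon (-0.15), inflammatory (0.07) and resident macrophage (-0.03) lists had intervals that included 0.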

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

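The tests of free RNA, of reads shared between genes, of acinar transcripts in cluster 6 and of naive genes in B cell-like cells were chosen only after the result was seen, as were list medians without cycling cells or with added T cells.

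Fixed gene lists lay on opposite sides of 0 in different classes, with intervals that excluded 0 on each side. Naive and memory T cell genes had medians of 0.16 in CD4 T cells and 0.25 in cluster 10, against -0.24 in cluster 6. Inhibitory receptor and exhaustion genes stood at 0.32 in cluster 6 and -0.31 in CD4 T cells, or -0.16 with the T cells of clusters 6 and 20 added to the latter. T cell homing receptors stood at 0.31 in cluster 10, -0.13 in CD8 T cells and -0.21 in CD4 T cells. The CD8 T side does not hold under every setting, since its median was 0.01 without cycling cells and 0.00 with the T cells of clusters 6 and 20 added. Type I interferon response genes stood at 0.28 in B cell-like cells and -0.16 in CD8 T cells. None of these differences between classes was tested.

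Clusters led by acinar and by stromal genes were present in the CD45.1 sort. At 12 weeks 11 cells were acinar cell-like and 20 stromal cell-like, and at 7 weeks 1 cell fell in each cluster. Of the 10 leading genes 10 and 8 differed between the ages within these clusters, so their sizes are not read as a difference between the ages. The stromal cell-like share difference also depended on the filter, at -0.206 points with at most 5% mitochondrial UMIs in place of 0.626. A Ptprc UMI, the transcript of CD45, was found in 8 of the 11 and 8 of the 20. The acinar cell-like cluster also had a UMI of the T cell gene Cd3e in 58.3% of its cells over both ages and of the B cell gene Cd79a in 25%, and acinar transcripts made up over 10% of UMIs in 3 barcodes at 12 weeks, so the cluster is not shown to be of acinar cells alone. Islet endocrine transcripts made up over 10% of UMIs in 5 barcodes at 12 weeks and in 1 at 7 weeks. The stromal cell-like cluster held 31918 of the 33255 Gcg UMIs and 14715 of the 15607 Ins2 UMIs at 12 weeks, so it is not of stromal cells alone.

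Acinar transcripts were higher at 12 weeks in every compared class. Doublets with acinar cells were argued against as the whole cause, since the 5% of 12 week CD4 T cells with the most acinar UMIs held 18.5% of them. Free RNA in the 12 week suspension remains a candidate explanation, because the level at 12 weeks was alike in CD8 T, CD4 T, B cell-like and cluster 10 cells, with the highest 1.12 times the lowest. For cluster 6, whose cells are deeper, this stays undecided, since CD8 T cells stood at 2.11 times its level (1.86 to 2.40), an interval that holds the limit of 2 set for the test. Whether the age of the mice or the islet preparation set the amount of free RNA was not tested, since age and library cannot be separated.

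A set of 46 genes was lower at 12 weeks in CD8 T, CD4 T and B cell-like cells alike, with medians of -1.21, -1.14 and -1.24. GC content of the 3' ends was argued against, as the B cell-like median was -1.35 after its subtraction. Reads shared with near copies were argued against for 15 members, of which 0% share 20% or more of their words with another gene. For the 31 ribosomal or unnamed members, of which 87.1% do, shared reads and a lower level of their own cannot be told apart. Such genes share words by nature, with 26.6% of those outside the set at or above the same limit. Those outside the set at or above it had a median of -0.11, against -0.01 for those below. A difference acting on every cell of a library remains open, since the median was -1.46 in macrophage-like cells and -1.28 in plasmacytoid dendritic cell-like cells, which had no part in the choice of the set, and a difference of age common to all of these cells was not tested.

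Naive and memory T cell genes were higher at 12 weeks in CD4 T cells. Free RNA was argued against, since the same list stood at -0.40 in B cell-like cells, and weakly positive cells were argued against, since it stood at 0.32 in the 209 and 474 cells with at least 2 Cd4 UMIs. Cluster 1 held 13.5% of CD4 T cells at 7 weeks and 31.2% at 12 weeks, and outside it the median was -0.13 (-0.33 to 0.02). A larger share of that cluster and higher naive genes within cells cannot be told apart, because this value lay outside both ranges set for the test and Lef1, Dapl1 and Ccr7 themselves lead the cluster. Outside cluster 1 Lef1 (1.35), Ccr7 (1.61) and Il7r (2.23) were still higher and Dapl1 (0.566) lower, and a biological difference with age may remain but was not tested.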

How the results depend on the processing

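The subtraction of GC content, the addition of the T cells of clusters 6 and 20, the removal of non-immune barcodes and, for lists, the removal of cycling cells were tests chosen only after the result was seen. No paired analysis was possible because each age had 1 library. Of 98 recomputed shares 91 stayed within the interval of the reported value, as did 2183 of 2350 gene ratios and 367 of 389 list medians. Keeping doublets, keeping every barcode, resolutions 0.5 and 2, thinning, named sub-clusters and added T cells moved no share difference they gave beyond its interval. With whole Foxp3 sub-clusters counted in place of cells with a Foxp3 UMI, the difference was -8.21 points (-4.89). Leaving out non-immune barcodes moved 0 of 60 lists. TMM or DESeq2 factors shifted all genes of a class by between -0.0829 and 0.0503 on the log2 scale. With each library clustered alone the share differences were -2.73 points for cluster 15 (-0.94 as reported), -1.71 for cluster 7 (0.401), 0.789 for conventional dendritic cell 1-like cells (-0.176) and 1.25 for innate lymphoid cell-like cells (-0.375). The macrophage-like difference, which was not read as a result above, was 1.61 in place of 0.0859. Over named leukocyte classes alone, without the unnamed clusters, the T cell-like difference was -4.63, by construction of the denominator. The clusters left out include cluster 6, where a Cd3e UMI was found in 99.2% of cells. At 5% mitochondrial UMIs or less the stromal cell-like difference was -0.206 (0.626). Without cycling cells log2 ratios reversed for Jchain (-0.48) in B cell-like cells, Stmn1 (-1.45) in cluster 10, Gzma (0.11) in CD8 T cells, and Tcf7 (1.08), Nkg7 (-0.62), Ikzf2 (2.35), Hspa8 (0.19), Ifi27l2a (-0.31) and Try5 (-0.60) in cluster 6, where few cells were left. Cd80 in B cell-like cells stood at -0.06, but it had 0 UMIs at 7 weeks. That value came from the floor of 3 counts and shows no reversal. List medians without cycling cells were 0.20 for cytotoxic genes, 0.01 for homing receptors (reversed from -0.13) and 0.19 for MHC class I genes in CD8 T cells, and 0.25 for antibody secretion and 0.22 for MHC class II genes in B cell-like cells. With the T cells of clusters 6 and 20 added, Gzma (0.95), Gzmb (0.06) and Tuba1b (-0.11) reversed in CD8 T cells, whose naive, cytotoxic and homing medians were 0.19, 0.27 and 0.00, and the inhibitory median of CD4 T cells was -0.16. With cells weighted equally Xaf1 in cluster 6 (0.21) reversed and Ube2c in B cell-like cells stood at 0.00. T subsets from sub-clusters gave -0.24 for the cell cycle in CD8 T cells. At 50 UMIs or more immediate early genes in CD4 T cells stood at -0.11 and regulatory genes in cluster 10 at -0.44 (0.75), with fewer members measured. At 1 UMI or more the lysosome list of cluster 7 stood at -0.08. TMM factors gave -0.09 for immediate early and 0.18 for MHC class I genes in CD4 T cells and 0.15 for the latter in cluster 6. With GC content subtracted, medians were 0.12 for MHC class I genes in cluster 6, 0.65, 0.09 and -0.07 for antibody secretion, MHC class II and interferon gamma genes in B cell-like cells, and 0.11 and -0.02 for MHC class II and lysosome genes in cluster 7. Except where construction is named, the cause was not tested. A class that a clustering did not name, some lists without cycling cells and 1 list at 50 UMIs gave no value. Depth limits genes with few UMIs at 7 weeks most, as their wide intervals show.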

Other observations

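All values here were chosen only after they were seen, and no tests were run on them.

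In CD4 T cells Ifng, encoding interferon gamma, was lower at 12 weeks at a ratio of 0.503 (0.440 to 0.575), and in CD8 T cells at 0.676 (0.565 to 0.812). After thinning, an Ifng UMI was found in 22.5% (17.7 to 27.95) and 19.0% (16.0 to 22.3) of CD4 T cells. In CD8 T cells the thinned shares were 34.1% (25.9 to 43.1) and 22.7% (18.6 to 27.2). Both pairs of intervals overlap, which does not show that the shares were alike. The thinned shares of B cell-like cells were 5.84% and 1.475%. Unthinned, the shares were 32.3% and 22.4% of CD4 T cells and 37.6% and 25.5% of CD8 T cells. Cd274, encoding the inhibitory ligand PD-L1, stood at 0.614 (0.457 to 0.827) in CD4 T cells, and Tnfrsf9, which was higher in CD8 T cells, at 0.618 (0.499 to 0.767). Lgals3, encoding galectin 3, stood at 0.536 (0.434 to 0.663) in CD8 T cells. Il21, encoding a helper T cell cytokine, stood at 0.993 (0.769 to 1.29) in CD4 T cells. Of 13 MHC class II genes 12 were higher in CD4 T cells, where Cd74 stood at 1.53 (1.31 to 1.79) and Cd79a at 3.02 (1.76 to 5.5).

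In cluster 7 the cell cycle list had a median of 1.60 (1.16 to 1.81), with 22 of 24 members higher, and cycling cells made up 9.84% and 16.3% of the cluster. In the same cluster Ccr7 stood at 4.47 (2.58 to 8.36), Fscn1, encoding an actin-bundling protein, at 2.03 (1.62 to 2.57) and the chemokine gene Ccl17 at 2.36 (1.53 to 3.76), with a UMI in 3.28% and 1.81% of cells. Ccl22, another chemokine gene, had 0 UMIs at 7 weeks and 78 at 12 weeks, 93.6% of them in 5 cells. Ccr7 is also expressed by B cells and T cells, whose transcripts differed between the ages in this cluster.

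Some secreted-factor transcripts sat in few cells. Ccl8, encoding a monocyte chemokine, had 82 UMIs in 2 of 16 macrophage-like cells at 7 weeks and 2781 UMIs in 18 of 43 at 12 weeks, with 1041 in 1 cell. CD4 T cells held 0 and 54 Ccl8 UMIs and B cell-like cells 0 and 45, with at most 2 in any cell. Cxcl13 had 0 and 1324 UMIs in macrophage-like cells, 937 of them in 1 cell, and 85 and 69 in CD4 T cells, with 70 in 1 cell at 7 weeks. Spp1, encoding osteopontin, had 1 UMI in CD4 T cells at 7 weeks and 226 at 12 weeks, from 23 of 738 cells with at most 45 in 1 cell, against 8 in B cell-like cells at 12 weeks. The stromal cell-like cluster, which also holds most Gcg and Ins2 UMIs of 12 weeks, had 532 Spp1 UMIs in 6 cells at 12 weeks.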
